A study of Mus musculus with 4 samples.

How the data were processed

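RNA from immortalized mouse embryonic fibroblasts was hybridised to 4 Affymetrix oligonucleotide arrays, 2 from PTIP -/- cells and 2 from PTIP +/+ cells. Per the labels' protocols, cells were kept in serum-containing medium and selected with puromycin, total RNA was taken up in Trizol and cleaned on a column, and a standard biotin label was used. The labels number the RNAs 1 and 2 within each genotype and do not say whether a number stands for a separate culture, infection or day. The p-values therefore measure only the spread between these RNAs, and what that spread stands for is not given in the sources used here.

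The deposited values are array intensities on a linear scale, with 1 value for each of 45101 probe sets on each array. The submitters' processing notes name RMA, with no version given, but the deposited intensities do not look like its usual output: they are linear, reach 0 for 1 probe set on 1 array, and have different quantiles on each array. Their mean after leaving out the top and bottom 2% was 500 on all 4 arrays, which is what scaling each array to a common trimmed mean gives. The background correction, the summary of probes into probe sets and the software version are not given in the sources used here. Scaling to a common mean leaves the medians free, and these were 97.8 and 82.5 in PTIP -/- replicates 1 and 2 and 83.2 and 75.8 in PTIP +/+ replicates 1 and 2. These medians overlap between the genotypes. A difference of that kind between arrays can move dim genes a little, so changes are read beside the median change of all genes, 0.05 on the log2 scale.

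Intensities were taken to log2 after the single 0 had been replaced by 0.1. The 64 control probe sets were left out. Of the rest, 34945 probe sets had 1 gene symbol in the platform annotation, 932 had several and 9160 had none, and only those with 1 symbol were named. Symbols were updated through the gene number of 34741 probe sets found in the RefSeq gene table of assembly GRCm38.p6, which was used for names alone. No genome build is named for the probe sets, so no positions are given. Each of 18193 genes was represented by its probe set with the highest mean over the 4 arrays. Genes were tested where that mean reached the 40th percentile of all probe-set means, a signal of 47.68, which kept 12509 genes and left out 5684. Among genes with several probe sets above that level, 2 of 5971 had probe sets that differed by at least 2-fold in opposite directions.

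PTIP -/- was compared with PTIP +/+ in limma 3.58.1 under R 4.3.3, with lmFit and eBayes on all 4 arrays, no covariate and 2 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested. A standard error is that of the moderated fit. It counts the difference between the replicate numbers as error, so the smallest p favours genes that differ little between the numbers. There are no detection calls among the values used here, so 47.68 was also taken as the lowest signal that can be read as a level, a choice made after seeing the data. Where every array of the dimmer group lay below it, those signals were raised to it and the fold is given as "at least". The same was done array by array for the comparisons within 1 replicate number, which set a single PTIP -/- array against a single PTIP +/+ array and carry no test. Where only 1 of the 2 arrays of that group lay below it, as for Paxip1, Gsta4, Dcn, Fst, Acan, Lyz2, Cxcl5, Fabp4, Hoxd11, Ddx4, Rhox5 and Trp53inp1, the fold or log2 change uses the measured signals.

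The 39 gene lists were fixed before the data were examined. They were tested with camera at its preset correlation of 0.01, two-sided, and adjusted over the 39 lists, with an estimated correlation and with fry beside it. A list's median within 1 replicate number was also placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins. Random lists take genes as independent, so these percentiles describe the arrays and are no test for lists whose genes move together. The genes named were set by a rule fixed before the data were examined: the members of the MLL3/MLL4 complex, the 12 genes with the smallest p in each direction if fewer than 10 passed (leaving out RIKEN, Gm, LOC and clone names), up to 4 passing members of each list or otherwise the member with the largest change, and the brightest member of each list of cell type markers. This gave 78 genes. Other genes are said to have been chosen after their values were seen.

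The alternatives tried were quantile normalization and median centring of the deposited values, no level filter and a filter at the 60th percentile, a variance trend with robust moderation, no moderation, the mean of a gene's probe sets, all probe sets, a 2-fold threshold, the replicate number as a block, each array left out in turn, and signals raised to 47.68 before log2. The model was tested on simulated data of 12509 genes in 10 runs, each with 200 changed genes. Drawn without any difference between the replicate numbers, 19.7%, 45.2% and 68.0% of genes changed by 1, 2 and 4 log2 units were called, and 49 of 933 calls were false. Drawn with the difference between the numbers found on these arrays, 0% was called at every size, with or without the block. A planted list of 20 genes shifted by -0.8 was called in 10 of 10 runs with the preset correlation, with 1 unchanged list called, and in 0 of 10 with the estimated one. The genes of these lists were drawn as independent and without any difference between the numbers. These counts therefore do not carry over to lists whose genes move together.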

Results

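The series asked which genes depend on PTIP in fibroblasts. PTIP, the product of Paxip1, is a BRCT-domain protein that sits in the MLL3/MLL4 histone methyltransferase complexes and also takes part in the DNA damage response. Immortalized mouse embryonic fibroblasts with both alleles of the gene flanked by loxP sites were infected with a retrovirus carrying Cre recombinase, which removes the flanked stretch, or with the empty vector. Both cell populations gave 2 RNAs, so that 2 PTIP -/- arrays stand against 2 PTIP +/+ arrays, and this number limits the precision of every value. Between 34.1% and 40.6% of probe sets lay below the level filter on each array. The 3' to 5' signal ratio of the actin control ran from 1.08 to 1.21 and that of the Gapdh control from 0.792 to 0.833.

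Paxip1 was close to background in the Cre-infected cells. Its brightest probe set read 43.5 and 74.6 in PTIP -/- and 1029.5 and 1040.1 in PTIP +/+. The mean log2 signal was 5.83 ± 0.55 (SD, n = 2) against 10.02 ± 0.01 (SD, n = 2), which is 18.2-fold lower in PTIP -/- and a log2 change of -4.18 ± 0.36 (SE). The arrays numbered 1 put it at least 21.6-fold lower and those numbered 2 at 13.9-fold lower. Its other probe sets, all below the filter in PTIP -/-, were at least 5.50-fold, 8.59-fold and 8.02-fold lower. With limma the adjusted p was 0.999 over all genes and 0.0025 adjusted over the list alone, the list being the complex PTIP belongs to. Which exons Cre removes, and whether these probe sets lie in them, is not given in the sources used here.

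On their brightest probe sets, the partners of PTIP in the complex differed by -0.30 to 0.59 log2. With 2 arrays per genotype these values cannot be told from no difference in this fit, which counts the difference between the numbers as error. With the replicate block no gene passed either. The values do not show unchanged levels. Kdm6a, an H3K27 demethylase, was 1.51-fold higher in PTIP -/- in both same-numbered comparisons, at 365.3 and 604.7 against 241.9 and 400.8 (log2 0.59 ± 0.43, SE). Kmt2d, the MLL4 methyltransferase, differed by 0.39 ± 0.29 (SE), Kmt2c, the MLL3 methyltransferase, by -0.11 ± 0.25 (SE) and Pagr1a, which binds PTIP directly, by -0.30 ± 0.28 (SE). A dim second probe set of Kmt2d gave -1.21, other probe sets of Kmt2c 0.15 to 0.24 and those of Pagr1a 0.02 and -0.68. Ncoa6, Dpy30, Rbbp5, Ash2l and Wdr5 lay between -0.15 and 0.16, and Ncoa6, Ash2l and Wdr5 turned from above to below 0 when arrays were centred on their medians. Apart from Paxip1, 0 members passed, over all genes or adjusted over the list alone. Of the 11 subunits of the SET1 and MLL complexes without PTIP, 7 were lower and 4 higher, the largest difference being that of Cxxc1 at -0.18 ± 0.32 (SE), with 0.17 on a second probe set. With camera neither list passed (adjusted p = 0.348 and 0.499), and fry gave adjusted p = 0.0304 for the PTIP-containing complex, the only list it called. That list holds Paxip1 itself, the deleted gene, and its other 9 members were 5 higher and 4 lower, so the fry result says nothing of the partners.

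Beyond Paxip1, the genes with the smallest p on the lower side included signalling and adhesion genes, some of them close to the filter in PTIP -/-. Ripor2, a RhoA regulator, read 123.6 and 67.1 against 1363.0 and 2191.1 (log2 -4.25 ± 0.45, SE). Inhbb, which encodes an activin subunit, was 12.5-fold lower (log2 -3.64 ± 0.44, SE), and Ak5, an adenylate kinase, 10.4-fold lower (-3.38 ± 0.46, SE). Fhdc1 was 4.62-fold, Wscd2 4.03-fold, Tgfbr3, a TGF-beta co-receptor, 3.79-fold, Itga8, an integrin chain, 3.68-fold, Igfbp4, a binding protein of insulin-like growth factors, 3.25-fold and Fam20c, a kinase of secreted proteins, 3.18-fold lower. Rasd2 and Brinp1, below the filter in both PTIP -/- arrays, were at least 4.02-fold and 3.50-fold lower. The size depended on the probe set for Ripor2 (others -1.24, -1.61 and -3.27), Inhbb (-1.51), Fam20c (-0.94) and Igfbp4 (-1.22 to -3.51), all on the lower side. All 12 of these genes, Paxip1 among them, were lower in both same-numbered comparisons by 2.88-fold or more. None passed after adjustment over all genes (adjusted p = 0.999 for each). Choosing genes by the smallest p on the same 4 arrays favours such agreement between the numbers, so it is no separate support.

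On the higher side the same rule took dimmer genes and smaller differences. Cmtm3, the brightest, read 2213.9 and 2489.0 in PTIP -/- against 1039.0 and 792.1, 2.59-fold higher. The glutathione transferase Gsta4 was 4.07-fold higher (log2 2.03 ± 0.41, SE), the cytokine Il18 2.70-fold, the acyl-CoA dehydrogenase family member Acad10 2.62-fold and Asb16 2.56-fold. For 7 others both PTIP +/+ arrays lay below the filter: Krt6a, a keratin, was at least 4.11-fold higher, Fam241b 2.84-fold, Dus2 2.51-fold, Dsg2, a desmosomal cadherin, 2.07-fold, the coagulation factor gene F13a1 2.06-fold, Ccpg1os 1.93-fold and Aanat 1.63-fold. The second probe sets of Dus2 and Krt6a, both dim, gave -0.16 and -0.41. All 12 genes were higher in both same-numbered comparisons, which the choice by smallest p again favours, with adjusted p = 0.999.

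**Figure D1:**
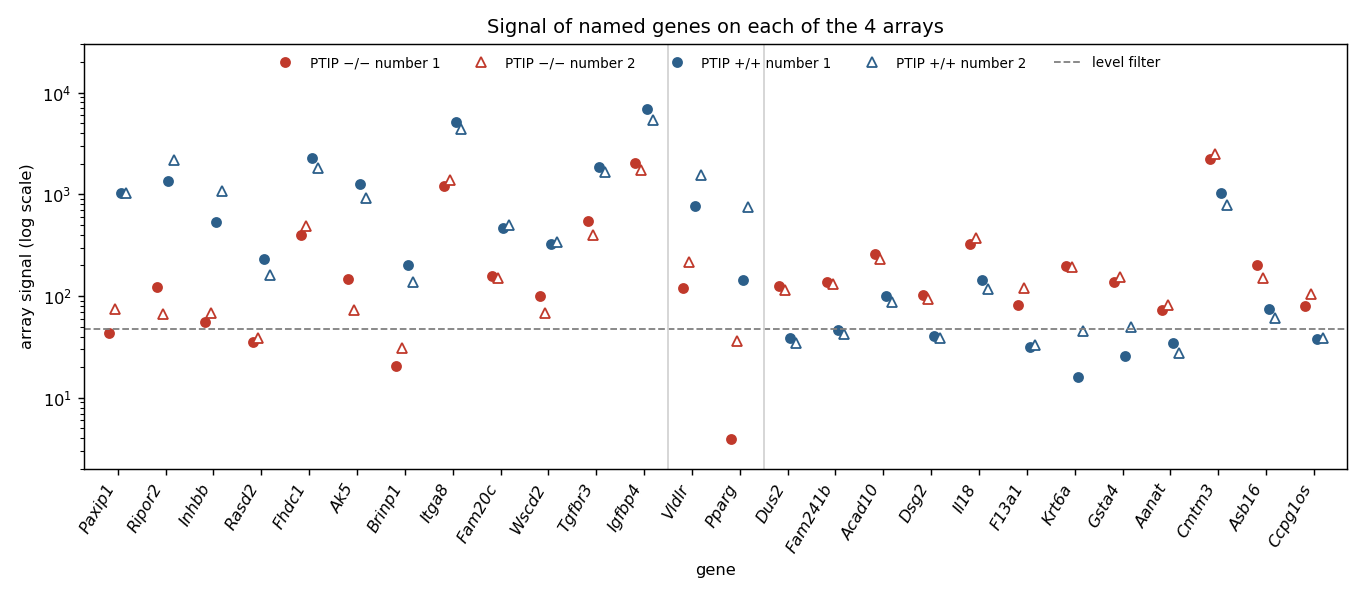
Signal on a log axis for the 12 genes with the smallest p on the lower side (left), Vldlr and Pparg (middle) and the 12 with the smallest p on the higher side (right), with 1 point per array and the level filter of 47.68 as a dashed line. Paxip1 reads 43.5 and 74.6 in PTIP -/- against 1029.5 and 1040.1 in PTIP +/+, and apart from Cmtm3 the genes on the right reach 376.1 at most.

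Of 12509 genes, 0 were higher and 0 lower at an adjusted p under 0.05 with limma. At an unadjusted p under 0.05 there were 168 higher and 118 lower, 286 in all. With no difference of any kind, 625.5 would be expected. That is no fair reference here, because the difference between the replicate numbers adds to the spread and raises the p-values. A crossed split, PTIP -/- replicate 1 and PTIP +/+ replicate 2 against PTIP -/- replicate 2 and PTIP +/+ replicate 1, carries the same difference and gave 81. The division into higher and lower depended on the scaling. It was 76 higher and 204 lower with arrays centred on their medians, which moves the median change of all genes by -0.18. With quantile normalization it was 116 and 144. An exact permutation test of a single gene cannot go below a two-sided p of 0.333 in this design.

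The spread behind this result followed the replicate number. Across genes, which are not independent replicates, log2 signals of the same-numbered arrays correlated at 0.969 (number 1) and 0.945 (number 2), and those of the same genotype at 0.904 (PTIP -/-) and 0.883 (PTIP +/+). The genotype differences within the 2 numbers correlated across genes with Pearson's r of 0.239 and Spearman's rho of 0.245. Within both numbers, 106 genes were at least 2-fold lower in PTIP -/- and 89 at least 2-fold higher, where independent lists would share 15.4 and 32.4. In opposite directions, 24 genes were 2-fold lower in number 1 and 2-fold higher in number 2, and 36 the reverse. These overlaps carry no test, and the higher count came to 57 once signals below 47.68 had been raised to it, against 90 lower.

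**Figure D2:**
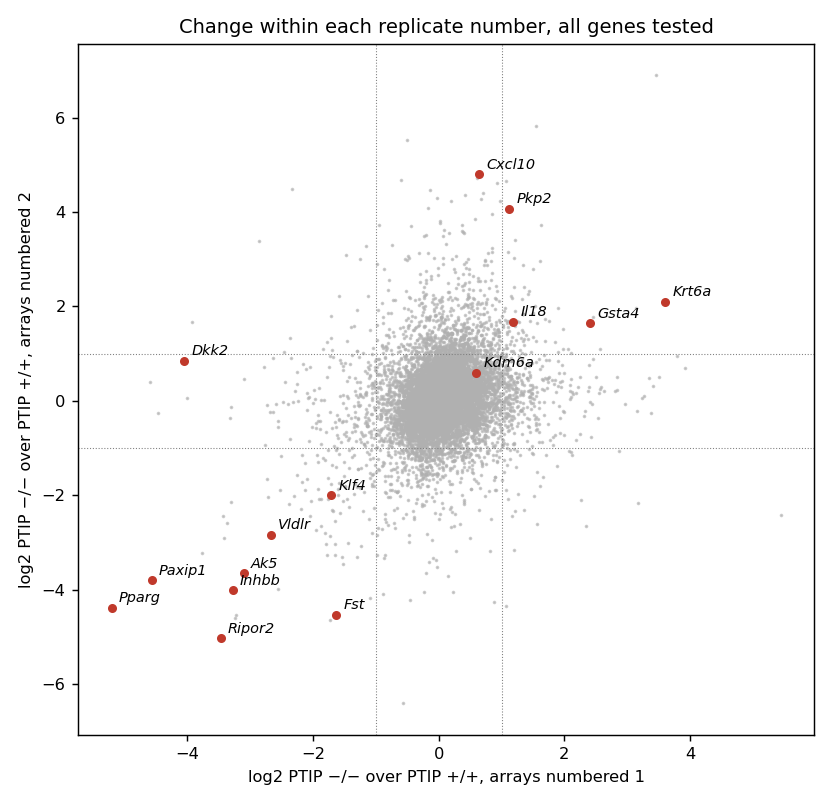
The log2 difference between PTIP -/- and PTIP +/+ in the arrays numbered 1 (x axis) against that in the arrays numbered 2 (y axis), 1 point for each of 12509 genes, with dotted lines at 2-fold and no correction of signals below the level filter. Paxip1, Ripor2, Inhbb, Ak5 and Vldlr lie far down on both axes, while Dkk2 is 16.5-fold lower in number 1 and 1.81-fold higher in number 2.

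Regulators of fat cell formation were lower in PTIP -/-, with Pparg, the nuclear receptor that directs adipogenesis, the farthest. Pparg read 3.9 and 36.0 against 143.1 and 750.0, at least 6.87-fold lower, with at least 3.00-fold in number 1 and 15.7-fold in number 2. Among members chosen after their values were seen, Klf4 was 3.62-fold lower (1589.5 and 655.3 against 5194.6 and 2625.9), and Cebpb and Cebpd, early factors of the same programme, 2.17-fold and 2.07-fold lower. Klf5, Klf2 and Dlk1 were 3.20-fold, 2.21-fold and 3.13-fold lower, so that 7 of the 16 tested members lay at least 1.5-fold lower within both numbers and 0 at least 1.5-fold higher. In all, 12 of the 16 were lower, with a median log2 change of -0.44 and -0.32 and -0.65 within the numbers. The list does not separate genes that promote fat cell formation from genes that inhibit it. Its shift therefore gives no direction for that process. Camera gave adjusted p = 0.000421 for the list, and adjusted p = 0.653 with an estimated correlation. With an estimated correlation the planted list of the simulated data was found in 0 of 10 runs. Failing that test, here and for the lists below, therefore does not show that a list is unshifted. Over 12 alternatives its adjusted p ran from 3.87e-05 to 0.0506, the last without PTIP +/+ replicate 2, and the median was -0.87 without PTIP +/+ replicate 1, -0.78 without PTIP -/- replicate 2 and -0.23 over the mean of a gene's probe sets. No member passed by itself, over all genes or adjusted over the list alone (0 and 0).

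Genes of the mature fat cell were split. Of 10 tested, 6 were higher and 4 lower, around a median of 0.03 that was -0.14 with centred arrays. Scd1, the brightest, differed by 0.05 ± 0.32 (SE), turning to -0.13 with centred arrays, and Fabp4 by -0.82 ± 3.42 (SE), its signal being set by the replicate number at 16.1 and 60.2 in number 1 and 4029.7 and 3351.8 in number 2, with 0.55 and -0.07 on dimmer probe sets. For this list camera gave adjusted p = 0.876, against a mean change of -0.08.

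Genes of DNA replication and mitosis were lower in PTIP -/-, all 29 tested members of either list. Tk1, a thymidine kinase of S phase, differed by -1.01 ± 0.45 (SE) and Prc1, which bundles spindle microtubules, by -0.92 ± 0.37 (SE). Mki67, chosen after its values were seen, read 3113.8 and 3001.6 against 4605.7 and 6254.9. The medians were -0.45 for replication and -0.42 for mitosis, and camera gave adjusted p = 2.27e-11 for both, and adjusted p = 0.653 for both with an estimated correlation. Most of the difference lay in number 2: replication genes had a median of -0.24 in number 1 and -0.77 in number 2, and mitosis genes -0.12 and -0.74. Among random lists matched on level, the number 1 medians stood at percentiles 0.02 (replication) and 5.93 (mitosis), and both number 2 medians at 0, and the difference between the numbers was not tested. Without PTIP -/- replicate 2 the medians were -0.23 and -0.23, and without PTIP -/- replicate 1 they were -0.78 and -0.68. Both lists were called under all 12 camera alternatives (adjusted p up to 0.0103 and 0.00289), while 0 members passed over all genes or adjusted over the list alone. Factors of the DNA damage response, several of which are made mainly in dividing cells, were lower in 19 of 23, led by Palb2 at -0.56 ± 0.30 (SE), with a median of -0.24 (adjusted p = 0.00209, and adjusted p = 0.741 with an estimated correlation). That call was lost without PTIP -/- replicate 2 (median -0.13), without PTIP +/+ replicate 1 (-0.17) and over the mean of a gene's probe sets (-0.12), the median was -0.41 without PTIP -/- replicate 1 and -0.42 with centred arrays, and the adjusted p ran from 0.000742 to 0.324.

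The amino acid supply genes driven by ATF4 gave, among the 11 lists called, the shift most alike in both numbers. In all, 16 of 17 were lower in PTIP -/-, with a median log2 change of -0.59 over all arrays, -0.56 in number 1 and -0.54 in number 2, at percentiles 0 and 0.01 of random lists. Vldlr, a lipoprotein receptor, was 6.73-fold lower at 121.3 and 218.0 against 769.0 and 1556.7 (log2 -2.75 ± 0.52, SE), with -1.54 and -0.97 on dimmer probe sets. Chosen after their values were seen, the serine synthesis enzymes Psat1 and Psph were 2.07-fold and 1.81-fold lower, asparagine synthetase, Asns, 1.60-fold and the pseudokinase Trib3 1.76-fold, each by at least 1.5-fold within both numbers. Atf4 itself was 1.24-fold lower and Ddit3, the 1 member above 0, 1.08-fold higher. Camera gave adjusted p = 4.03e-10, and adjusted p = 0.653 with an estimated correlation, and the list was called under all 12 alternatives (adjusted p up to 0.000115, median from -0.77 to -0.45). The smallest p adjusted over the list alone was 0.09, so 0 members passed there or over all genes.

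Ribosomal protein genes were slightly lower, all 19 tested, by a median of -0.23, Rpl14 farthest at -0.39 ± 0.30 (SE). Camera gave adjusted p = 0.000451, and adjusted p = 0.653 with an estimated correlation. Quantile normalization ended the call (median -0.09, adjusted p = 0.294, in a range from 1.77e-08), as did leaving out PTIP +/+ replicate 2 (-0.13), and centring the arrays gave -0.41. Ribosome biogenesis genes had a median of -0.14, with Fbl, the nucleolar methyltransferase, at -0.53 ± 0.28 (SE), and only just passed (adjusted p = 0.0484, and adjusted p = 0.87 with an estimated correlation). Their median was -0.28 in number 1 and -0.01 in number 2 and lay above 0 without PTIP -/- replicate 2 (0.13) or without PTIP +/+ replicate 1 (0.29), at -0.45 without PTIP -/- replicate 1, at -0.59 without PTIP +/+ replicate 2 and at -0.32 with centred arrays. That call held under 6 of 12 alternatives, with an adjusted p from 4.36e-07 to 0.842. In the unfolded protein response list 12 of 17 were lower, Atf6, a stress sensor, by -0.67 ± 0.29 (SE) and by -0.35 on a second probe set, but the list did not pass (median -0.24, adjusted p = 0.0518). It passed under some alternatives, among them a variance trend, which also called cholesterol synthesis genes downward.

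Most collagen and matrix, immediate early and Wnt genes were lower in PTIP -/-. Among collagens and other matrix genes, 21 of 28 were lower around a median of -0.31. Dcn, a small proteoglycan, read 242.7 and 18.7 against 1266.0 and 84.5, 4.86-fold lower. Col11a1 and Col12a1, chosen after their values were seen, were 4.73-fold and 2.39-fold lower. Egr1, a serum-induced transcription factor, was 2.37-fold lower (log2 -1.25 ± 0.44, SE), and 17 of 21 immediate early genes were lower around a median of -0.40. In the Wnt list 13 of 16 were lower, with a median of -0.46. Its farthest member, Dkk2, read 82.7 and 608.1 against 1367.9 and 336.8, in opposite directions in the 2 numbers, whereas Ccnd1, cyclin D1, chosen after its values were seen, was 3.10-fold lower in number 1 and 2.63-fold lower in number 2. Camera gave adjusted p = 0.000421 for matrix, 0.00153 for immediate early and 0.00311 for Wnt genes, and adjusted p = 0.653 for each with an estimated correlation. Members that passed over all genes or adjusted over the list alone numbered 0 in each of the lists.

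Those calls were lost under single settings, though each held with the replicate block. As for every list, leaving out 1 array also leaves the replicate numbers unequal between the genotypes. A median can then move with the difference between the numbers. The matrix list was lost with quantile normalization (median -0.18, adjusted p = 0.0573, in a range from 2.5e-06), and its median was -0.49 without PTIP +/+ replicate 1 and with centred arrays, and -0.20 without PTIP +/+ replicate 2. Immediate early genes were lost without PTIP -/- replicate 1 (-0.06) and PTIP +/+ replicate 1 (-0.20, adjusted p = 0.143, in a range from 3.87e-05), with -0.16 without PTIP -/- replicate 2. Wnt genes were lost without PTIP +/+ replicate 1 (-0.49) and with the stricter filter (-0.84, adjusted p = 0.113, in a range from 0.00189), and stood at -0.20 without PTIP -/- replicate 2.

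Interferon-stimulated genes were higher in PTIP -/- in the arrays numbered 2. There 19 of 22 tested members were higher, with a median of 0.94, at percentile 100 of random lists matched on level. In number 1, 11 were higher and 11 lower around 0.00, at percentile 20.74, and the difference between the numbers was not tested. Cxcl10, a chemokine, read 132.4 and 153.9 in PTIP -/- against 85.1 and 5.5, 1.56-fold higher in number 1 and at least 3.23-fold higher in number 2. Usp18 and H2-K1, chosen after their values were seen, read 131.0 and 630.1 against 190.2 and 78.3, and 2632.8 and 5587.8 against 1731.9 and 2055.0. Over all 4 arrays camera called the list upward (median 0.44, adjusted p = 0.0236, and adjusted p = 0.764 with an estimated correlation), with 0 members passing over all genes or adjusted over the list alone. The median was -0.07 without PTIP -/- replicate 2 and 0.87 without PTIP -/- replicate 1, the call was also lost without PTIP +/+ replicate 2 (0.41) and without the level filter (0.36), and centring gave 0.27. Its adjusted p ran from 2.31e-06 to 0.859.

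No other signalling or metabolic list passed over the 4 arrays. Of 23 p53 targets, 17 were higher (median 0.37, adjusted p = 0.499), Trp53inp1 farthest at 3.81-fold with signals that followed the number, 145.9 and 39.3 in number 1 and 3689.3 and 944.6 in number 2. Inflammatory genes had a median of 0.16 (Cxcl5, 2.11 ± 1.83, SE), oxidative stress genes one of 0.06, TGF-beta and BMP targets one of -0.10 (Fst, an activin antagonist, 8.47-fold lower), Notch targets -0.25 (Nrarp, 2.62-fold lower), Hedgehog targets -0.12 (Foxf1, -0.62 ± 0.78, SE, and -1.36 on a second probe set) and imprinted genes -0.12 (Slc38a4, 3.45-fold lower). Slc38a4 was 1.11-fold lower in number 1 and 10.7-fold lower in number 2, and its sign turned in at least 1 alternative. Cholesterol synthesis genes went in opposite directions: 17 of 19 were higher in number 1 (median 0.32) and 19 of 19 lower in number 2 (median -0.77), Pmvk by -0.69 ± 0.41 (SE) over all arrays. Glycolysis and hypoxia genes had medians of -0.35 in number 1 and 0.16 in number 2, with Adm, adrenomedullin, 4.17-fold lower over all arrays. Adm was 1.81-fold lower in number 1 and 9.59-fold lower in number 2. Medians were -0.05 for oxidative phosphorylation (Cox5b, -0.31 ± 0.31, SE), -0.05 for contractile genes (Ankrd1, 1.65 ± 2.12, SE), -0.01 for matrix proteases (Plat, 3.49-fold higher), -0.10 for clock genes (Cry2, -0.85 ± 0.69, SE), 0.27 for histone genes (H1f2, 2.54-fold higher) and 0.16 for Hox genes (Hoxd11, -0.88 ± 3.02, SE). H1f2 was 1.38-fold higher in number 1 and 4.68-fold higher in number 2. The medians of Hox genes (-0.02), inflammatory genes (-0.02) and oxidative stress genes (-0.12) turned below 0 with centred arrays, and those of Hox genes (-0.05) below and of matrix protease (0.04) and contractile genes (0.07) above 0 with quantile normalization. Leaving out PTIP -/- replicate 1 gave calls for p53 targets (0.63), Notch targets (-0.70) and glycolysis (-0.32), leaving out PTIP +/+ replicate 1 for imprinted (-0.33), Hox (-1.54) and cholesterol genes (-0.79), and leaving out PTIP +/+ replicate 2 for p53 targets (0.47), glycolysis (-0.52), Hox (1.30) and cholesterol genes (0.35). Leaving out each array turned the sign of all 6 of these lists at least once, with medians from -0.30 to 0.63 for p53 targets, -0.70 to 0.08 for Notch targets, -0.52 to 0.28 for glycolysis and -0.33 to 0.39 for imprinted genes.

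Markers of other cell types showed no list shift past the threshold. Skeletal muscle markers were higher in 6 of 6 tested (median 0.50, adjusted p = 0.107), the largest and brightest being Acta1 at 152.8 and 8870.4 against 175.7 and 1850.3. Epithelial markers had a median of 0.21, with Pkp2, a desmosomal plaque protein, 6.05-fold higher (log2 2.60, and 0.84 on a dimmer probe set), and cartilage and bone markers 0.22, with Acan, the cartilage proteoglycan, 2.92-fold lower and Omd, the brightest, at 0.42 ± 0.70 (SE). Pkp2 was 2.18-fold higher in number 1 and 16.8-fold higher in number 2, where PTIP +/+ read 86.5. Flt1, a VEGF receptor, was 4.47-fold lower among endothelial markers (log2 -2.16, and -4.43 and -1.10 on other probe sets) while Eng, the brightest, differed by 0.07. Medians were 0.09 for endothelial, 0.07 for macrophage (Lyz2, 2.46-fold higher, and Csf1r, 0.03), 0.12 for neural (Dcx, at least 1.39-fold higher, and Ncam1, -0.17), 0.09 for mesothelial (Krt19, 2.92-fold lower, and Cdh3, 0.91), 0.14 for pluripotency (Dppa5a, 0.38, and Fgf4, 0.13) and 0.47 for germline genes (Ddx4, 0.72, and Rhox5, -0.49). With centred arrays Eng, Csf1r and Fgf4 turned below 0, as did the medians of the endothelial, macrophage, neural, mesothelial and pluripotency lists, and these 5 medians and that of cartilage and bone markers were also below 0 with quantile normalization. Median, mean and camera direction differed in sign for 7 lists: fat cell, Hox, matrix protease, contractile, germline, endothelial and mesothelial genes. Across the 28 lists that camera did not call, adjusted p ran from 0.0518 to 0.989, and 0 members other than Paxip1 passed over all genes or adjusted over the list alone.

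**Figure D3:**
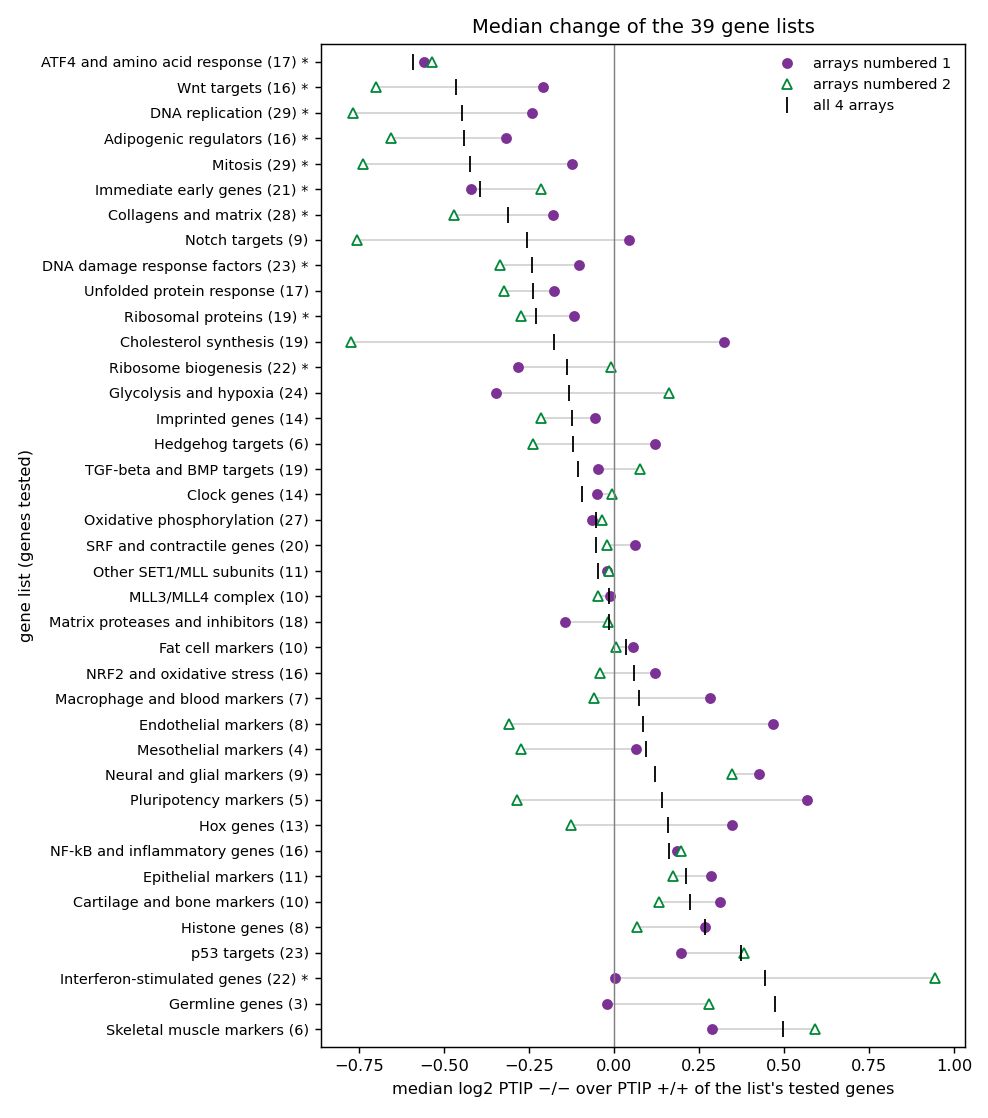
Median log2 difference between PTIP -/- and PTIP +/+ of each of the 39 lists within the arrays numbered 1 (filled circles), those numbered 2 (open triangles) and all 4 arrays (bars), with the number of genes tested in brackets and a star for lists called by camera with its preset correlation. The ATF4 list lies at -0.56 and -0.54 in the 2 numbers, whereas cholesterol synthesis lies at 0.32 and -0.77. With an estimated correlation 0 of the 39 lists pass, a test that also found the planted list of the simulated data in 0 of 10 runs.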

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

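The floor, the block fitted with trend and robust moderation, the medians within each number and the counts of genes 2-fold in both numbers were chosen after seeing the data, and the rest were planned. Under all 16 alternatives fitted over genes, 0 genes passed in either direction (smallest adjusted p 0.0728), with 64 to 612 higher and 81 to 584 lower at an unadjusted p under 0.05. Paxip1 ran from -5.18 to -3.79 over 14 alternatives. Of the other 77 named genes, 52 kept their sign under all 14 alternatives fitted to single genes and 25 turned in at least 1. Camera called 8 to 13 lists over 12 alternatives, 0 with an estimated correlation and 1 with fry, a test that does not compare a list with other genes. Leaving out each array gave medians from -0.075 to 0.87 for interferon, -0.59 to 0.29 for ribosome biogenesis, -1.54 to 1.30 for Hox and -0.79 to 0.35 for cholesterol genes. Of the 39 lists, 21 had medians of both signs when each array was left out. The arrays left then hold unequal numbers of each replicate number, and the lone array is assumed to vary like the other group. Against 89 genes at least 2-fold higher and 106 lower in both numbers, there were 57 and 131 with quantile normalization, 40 and 154 with centring, 545 and 295 without the filter, 34 and 77 with the stricter filter, 92 and 82 with the mean of a gene's probe sets and 57 and 90 with the floor. The filter sets how many dim genes are counted. Centring moves the change of every gene down by the same amount, -0.18 over all arrays, which by itself lowers the higher count and raises the lower one. For quantile normalization the cause was not tested. With the replicate block, 0 genes were higher and 0 lower (smallest adjusted p 0.601, with 612 and 370 at an unadjusted p under 0.05), Paxip1 stayed at -4.18 and 12 lists were called, the 11 and the unfolded protein response. Adding trend and robust moderation to the block also gave 0 and 0. Same-numbered arrays deviated from their group means together (r = 0.686 across genes), but with 2 numbers and no label saying what they mark, they were not taken as pairs. The standard errors and p-values of the Results therefore count this shared difference as error. No list test without moderation or over all probe sets was run, and list tests took the variance trend without robust moderation. Signal over background limits the genes at or under 47.68: folds are bounds where a whole group lies there and rest on a signal near background where 1 array does.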

Other observations

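The gene lists were fixed before the data were examined, and the tests of the numbers, of the cell cycle lists and of the interferon list given here were chosen after the results had been seen. Genes named in this part were chosen after their values were seen.

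The arrays numbered 1 and 2 differed in some Hox genes of the A and D clusters. Hoxa5 did not share this, at 220.2 in PTIP -/- and 217.6 in PTIP +/+ of number 1 and 243.5 and 197.8 in number 2. Among the 13 Hox genes tested, some of which passed the level filter through number 2 alone, the median of number 2 over number 1 was 2.63 log2 in PTIP -/- and 3.11 in PTIP +/+, and 8 were at least 2-fold higher and 0 at least 2-fold lower in both genotypes. Over all 32 on the array the medians were 0.97 and 0.30, with 11 genes below the filter on every array. Once signals below 47.68 had been raised to it, the medians over these 32 were 0 and 0, and 8 genes stayed at least 2-fold higher in both genotypes. Hoxd13, a homeobox gene of the distal limb and tail end, read 7369.9 in PTIP -/- and 7643.8 in PTIP +/+ of number 2, and 42.0 and 26.3 in number 1, at least 157-fold apart. Hoxa10, Hoxd10 and Hoxd11 were at least 27.1-fold, 17.6-fold and 11.5-fold higher in number 2, and Bmp4, a growth factor of limb mesenchyme among other sites, 110-fold higher. Other developmental transcription factors went both ways. Tfap2b was at least 39.98-fold and Msx1 28.7-fold higher in number 2. Some were high in number 1: Alx1, which acts in facial mesenchyme, read 991.7 and 793.3 against 2.6 and 4.0, Lhx8 2067.2 and 1483.8 against 18.0 and 2.8, and Pax3, which acts in neural crest and muscle precursors, 1765.4 and 833.8 against 20.1 and 9.3. Crabp1, a retinoic acid binding protein, was at least 91.5-fold and Thy1, a fibroblast surface protein, 25.8-fold higher in number 1. At least 4-fold in both genotypes, 196 genes were higher in number 2 and 104 in number 1.

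Single genes known from other tissues also differed between the numbers. Col10a1, the collagen of hypertrophic cartilage, read 18330.3 and 5786.5 in number 2 against 8.0 and 3.3 in number 1, Fabp4, the fatty acid carrier of fat cells, 4029.7 and 3351.8 against 16.1 and 60.2, and the germ cell helicase Ddx4 473.7 and 390.5 against 9.0 and 4.0. The fat cell list as a whole had a median of -0.09 in number 2 over number 1 in PTIP -/- and -0.34 in PTIP +/+. Grb10, an imprinted gene, was 113-fold higher in number 2, while Cdkn1c, another imprinted gene, read 1543.7 and 2135.9 in number 1 against 69.8 and 22.9.

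Same-numbered arrays resembled each other more than arrays of the same genotype. Splitting the 4 arrays by number called 82 genes in limma at an adjusted p under 0.05, where splitting by genotype called 0. At an unadjusted p under 0.05 there were 2546 by number, 286 by genotype and 81 by the crossed split. The last 2 counts are held down by the difference between the numbers, which adds to their spread. A difference in scanning or scaling as the only source is argued against by the spiked-in control probe sets. Their median absolute difference between the numbers was 0.07 log2 (95% bootstrap interval 0.044 to 0.092, 42 probe sets), against 0.313 for 8172 genes of the same signal range. The bootstrap takes these probe sets as independent. Controls added at different steps were pooled, so the values cannot speak on labelling. The spike-ins say nothing of what happened before they were added. A hypothesis is that the numbers mark cultures derived from different embryonic tissue, each infected with both viruses. The 13 tested Hox genes had a median absolute difference of 2.93 log2, at percentile 100 of random lists matched on level. Some of them passed the level filter through number 2 alone, which raises that median. Neither the percentile nor its place as the largest of the 39 list medians (next 1.60) can therefore count for the hypothesis. Over all 32 Hox genes on the array, with signals raised to the floor, the median of number 2 over number 1 was 0 in both genotypes. Many of these genes are dim, 11 lying below the floor on every array, and a gene below it in both numbers gives 0. That median therefore cannot count against the hypothesis either. With the floor, 8 of the 32 were at least 2-fold higher in number 2 in both genotypes and 0 at least 2-fold lower. Besides, 5 other lists also reached percentile 100, which cannot rank them, so this hypothesis and the same cells drifting apart in culture both stay open.

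Lower replication and mitosis genes may come from number 2 alone or from both numbers. The number 1 median stood at percentile 0.02 of random lists for replication and at 5.93 for mitosis. Random lists take genes as independent, while these genes move together (estimated correlation 0.58 and 0.61), and cholesterol genes stood at percentiles 100 and 0 in the 2 numbers, so the percentiles do not decide and both possibilities stay open. Between the PTIP -/- arrays, number 2 differed from number 1 by a median of -0.58 for replication and -0.46 for mitosis. Between the PTIP +/+ arrays it differed by 0.04 and 0.36. For mitosis both genotypes thus differed between the numbers, in opposite directions. These values cannot say whether the arrays numbered 1 or those numbered 2 depart. Slower growth without PTIP, which the design could give, and unequal growth of both cultures of number 2 stay open.

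Higher interferon-stimulated genes may be a property of the number 2 cultures, but the percentiles do not decide this either, with an estimated correlation of 0.227. Their number 1 median stood at percentile 20.74 of random lists and their number 2 median at percentile 100. In PTIP -/- the list was higher in number 2 than in number 1 by a median of 0.80 (percentile 100), and in PTIP +/+ it was -0.21 (percentile 17.78). A response to the virus or culture in that array and an effect of PTIP loss seen only in those cells both stay open.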
